A study of Mus musculus with 6 samples.

How the data were processed

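RNA was measured in NIH3T3 cells, a line of mouse embryonic fibroblasts, by sequencing of 6 libraries. Per the labels, 3 libraries came from wild-type cells and 3 from cells overexpressing the Nogo-B receptor NgBR, whose gene is Nus1. Per the labels' protocols, the overexpressing cells were stably transfected with an HA-tagged NgBR plasmid and selected with G418, and both lines were grown in medium with 10% calf serum. The species of the NgBR coding sequence in the plasmid is not given in the sources used here. Total RNA was isolated on columns and 1.5 micrograms per sample entered a SMARTer mRNA-seq library preparation, per the labels' protocols. Knockdown lines named in the same protocols were not analysed here. The replicates are numbered 1 to 3 in the titles of both groups, and the labels do not say whether they came from separate cultures, so that p-values measure only the spread between these libraries, which may be technical.

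The deposited values were raw counts per gene, whole numbers with no normalization. Per the submitters' processing notes, the tools were HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2, with genome build mm10. The annotation release, the strand setting and any filter are not given in the sources used here. Reads from overlapping or antisense genes, and from near-identical copies such as pseudogenes, can therefore have been assigned to either gene. The table held 35275 genes, all with mouse Ensembl identifiers, and no sample columns beyond those of the 6 libraries. Gene positions, classes, exonic lengths and GC contents were taken from a GENCODE annotation of the same assembly, which held 97.8% of the identifiers.

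Differential expression was tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test on the counts with TMM factors and no covariate. Genes were kept by filterByExpr with the group, which left 12651 genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and fold changes are those of the libraries labelled NgBR overexpression over wild type. CPM values were computed on TMM-scaled library sizes and are given as mean ± SD over n = 3 libraries per group. For a gene with 0 counts in a whole group, the fold is a lower bound against 3 counts over that group. For a gene with 1 to 3 counts, the ratio of pooled counts is given with an exact 95% interval. Intervals and bounds cover counting error only, since reads without molecular identifiers are not independent molecules.

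The 37 gene lists were fixed before the data were examined, as were the groups, the tests and the alternatives except those named as later. The 33 lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2. Its preset correlation between genes of 0.01 gave the calls, and p-values were adjusted over the lists. camera with an estimated correlation and fry, a rotation test of whether a list moves one way, were run beside it. The number of called members is given over all tested genes and adjusted over the list alone. The genes named by rule were Nus1 and its partner Dhdds, and the 10 called genes with the largest fold change in each direction. These needed a mean of at least 5 CPM, separate ranges of the groups and a symbol that is not one of a predicted gene. The rule also took up to 4 called members of each list with a mean of at least 1 CPM, or its most abundant members, and the 5 most abundant genes. Genes named outside it were chosen after their values were seen, and some genes that the rule takes are not reported here.

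The fits and list tests were tested on simulated data with the means, spread and depth of these libraries. Of 100 genes changed 2-fold, 16.0% were called, and of 100 changed 4-fold, 86.0%, among 12471 simulated genes. Of 111 calls, 9 were unchanged genes and 0 had the wrong sign, and 0 of 30 unchanged lists were called. Genes were drawn independently of each other, so that the simulation does not test list calls among correlated genes.

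The alternatives were DESeq2 1.42.0, limma-voom, a robust dispersion fit, RLE, upper-quartile and no composition factors, and removal of the 10 most abundant genes. No filter on low counts, a minimum of 1 CPM in 3 libraries, a test against a 1.5-fold change, the replicate number as a block and each library left out in turn were also run. Thinning of all libraries to the depth of the shallowest, offsets for exonic length and GC content, leaving out both libraries numbered 2, and a fit of protein-coding genes only were added after the data were seen. Parent genes of processed pseudogenes were found with BLAST 2.17.0 against protein-coding transcripts.

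Depth differed between the groups. The total counts were 35511769, 29515072 and 32196873 in wild-type libraries 1 to 3, and 7369961, 10358381 and 10082223 in the libraries labelled NgBR overexpression. A count of 3 over the latter group corresponded to 0.108 CPM, which sets the lowest level that could be resolved there. No library was left out of the main comparison. Pairs of libraries were compared by a chi-square test of their counts, and the smallest chi-square per degree of freedom was 27.7, so that no pair agreed within sampling noise.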

Results

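Transcript levels were measured in 6 RNA-seq libraries of NIH3T3 mouse fibroblasts, 3 of wild-type cells and 3 labelled NgBR overexpression. NgBR, the Nogo-B receptor, is encoded by Nus1 and forms cis-prenyltransferase, the enzyme of dolichol synthesis, together with the product of Dhdds. Wild-type libraries held between 29515072 and 35511769 counts and the libraries labelled NgBR overexpression between 7369961 and 10358381, a 3.50-fold difference in mean depth that runs with the groups. The first principal component took 46.5% of the variance and separated the groups. The second, with 28.6%, set both libraries numbered 2 apart, at -35.0 and -52.0, from the other 4 libraries. Across genes, the deviation of log2 CPM from the mean of the 6 libraries was correlated with exonic length (Spearman). The values were 0.242 and 0.347 in wild-type and labelled library 2, and -0.226 and -0.299 in wild-type libraries 1 and 3. They were 0.0684 and -0.467 in labelled libraries 1 and 3. Mitochondrially encoded genes took 1.10 ± 0.397% of the counts in wild-type libraries and 0.649 ± 0.237% in the others. Yam1 took between 0.135% and 3.40% of a library, with 250778 counts in labelled library 1 against 13964 and 32203 in labelled libraries 2 and 3.

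**Figure D1:**
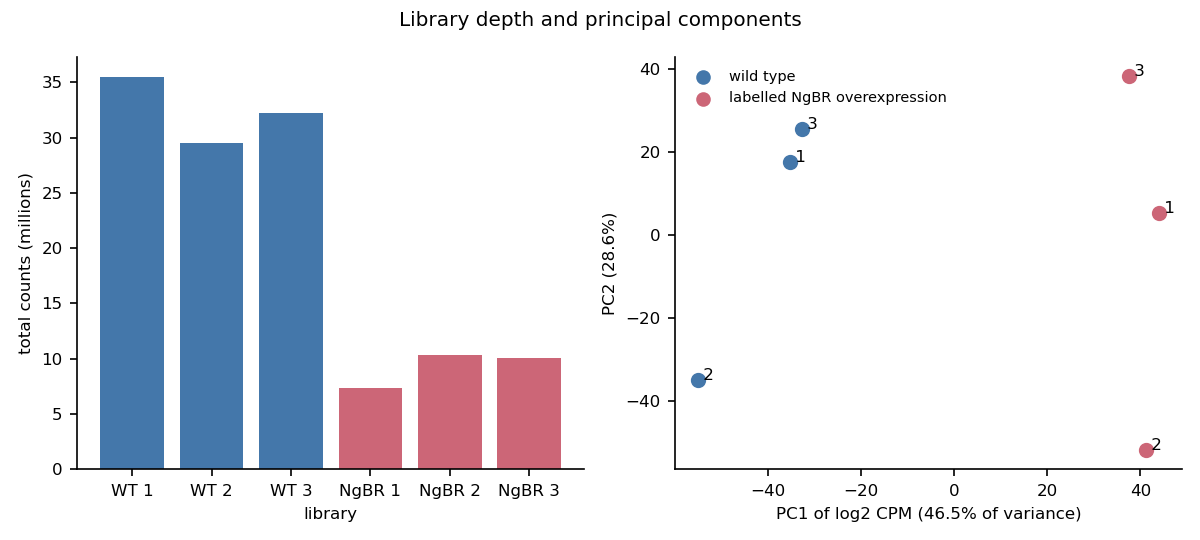
Total counts per library (left, bars from 0) and the first principal components of log2 CPM, 1 point per library with its replicate number (right). The libraries labelled NgBR overexpression held 7369961 to 10358381 counts against 29515072 to 35511769 in wild type, and both libraries numbered 2 lie lowest on the second component.

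The design asks how raised NgBR changes the transcriptome of these fibroblasts, and Nus1 was examined first as a check of the labels. Nus1 (ENSMUSG00000023068, mm10 chromosome 10, 52417547 to 52440183, plus strand, protein-coding) was measured at 212, 187 and 233 CPM in wild-type libraries 1 to 3. It was at 184, 185 and 165 CPM in the libraries labelled NgBR overexpression. The means were 211 ± 22.8 and 178 ± 11.0 CPM (SD, n = 3 each), a log2 fold change of -0.24 (SE 0.21, 95% interval -0.72 to 0.24) with adjusted p = 0.786 by edgeR's quasi-likelihood test. Counts at mouse Nus1 thus did not rise with the label. They do not decide on it, since reads of the transgene may not have been counted there. Every direction given here is that of the libraries labelled NgBR overexpression relative to wild type. Dhdds was at 36.7 ± 11.0 and 37.8 ± 5.09 CPM, a log2 fold change of 0.04 (edgeR adjusted p = 0.985). Its sign turned without wild-type library 2 (-0.18) and without library 1 labelled NgBR overexpression (-0.05).

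**Figure D2:**
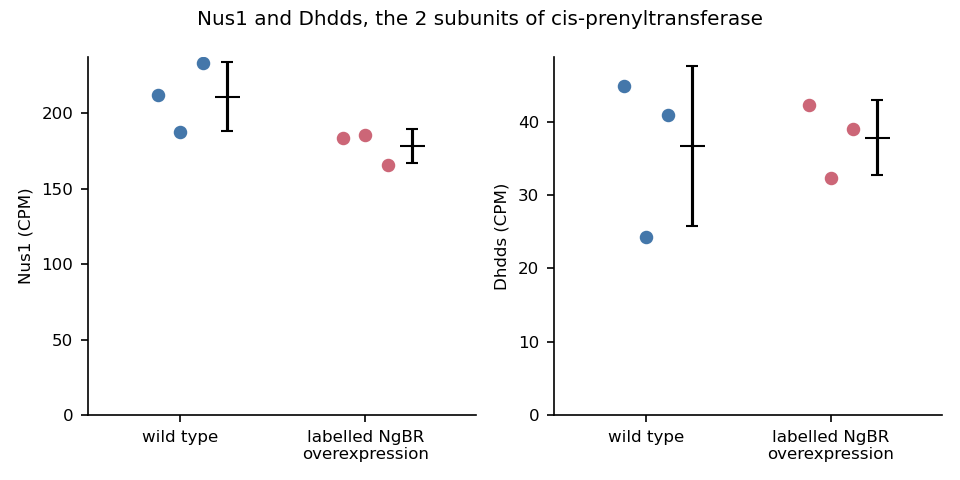
CPM of Nus1 (left) and Dhdds (right), 1 point per library, with mean and SD of 3 libraries per group as bars, on axes from 0. Nus1 lay between 165 and 185 CPM in the libraries labelled NgBR overexpression and between 187 and 233 CPM in wild type.

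The largest changes between the groups were near-complete losses of single transcripts and gains of others from low levels. Tgfbi, a matrix protein induced by TGF-beta, fell from 21 ± 2.15 CPM to 0 counts, at least 194-fold lower, and Lum, the proteoglycan lumican, from 23.2 ± 2.41 CPM to 1 count. Kctd12, an auxiliary subunit of GABA-B receptors, rose from 1.48 ± 0.137 to 48.1 ± 33.9 CPM, and Pou4f1, a transcription factor of sensory neurons, from 1.17 ± 0.276 to 27.9 ± 8.43 CPM (SD, n = 3). In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 429 of 12651 genes (3.39%), 258 higher and 171 lower, of which 427 changed at least 2-fold, and DESeq2 called 726. Of the genes called higher, 29 were processed pseudogenes, whose counts are uncertain where reads are shared with a parent gene. The CPM ranges of the groups did not overlap for 18.6% of the genes. Libraries without a group difference would give 10% on average over splits. Genes are not independent of each other, so that a single split can lie far from this average, and the excess is no test of the groups. The number of calls fell to 250 without wild-type library 1, 225 without library 1 labelled NgBR overexpression and 274 without library 3 so labelled. The genes called higher numbered 141 without wild-type library 1, 164 without wild-type library 3 and 141 without labelled library 1, and those called lower 109, 84 and 102 without wild-type library 1 and labelled libraries 1 and 3.

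The ranks below cover called genes within the limits of the naming rule, such as a mean of at least 5 CPM. Among the 10 with the largest decrease, Slc6a15, Ndn and Epb4.1 also had 0 counts in the libraries labelled NgBR overexpression. Slc6a15 encodes a neutral amino acid transporter, Ndn is the imprinted gene of necdin, and Epb4.1 encodes a membrane skeleton protein. They were at least 127-fold, 121-fold and 97.3-fold lower. The pooled wild-type to labelled ratio of Lum was 641, with a counting interval of 115 to 2.53e+04, and its 1 count lay in labelled library 1. Gas6, the ligand of the AXL receptor, fell from 24.2 ± 3.32 to 0.196 ± 0.198 CPM (log2 fold change -6.78, SE 0.50, edgeR adjusted p = 0.000294). Meg3, an imprinted long noncoding RNA, fell from 31.6 ± 5.57 to 0.471 ± 0.566 CPM (log2 fold change -6.24, SE 0.58, edgeR adjusted p = 0.000734). Phactr2, Dapk1, the gene of death-associated protein kinase, and Serpina3g had log2 fold changes of -6.38, -5.69 and -5.52. Without labelled library 1 the value of Meg3 was -7.72, without labelled library 2 those of Gas6 and Dapk1 were -7.68 and -6.35, and without labelled library 3 that of Phactr2 was -7.0.

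Kctd12 and Pou4f1 were among the 10 genes with the largest increase under the same limits. Their log2 fold changes were 5.01 (SE 0.52, edgeR adjusted p = 0.00119) and 4.57 (SE 0.35, edgeR adjusted p = 0.00034). Cadm1, a cell adhesion molecule, rose from 0.540 ± 0.138 to 14.7 ± 6.16 CPM and Rarb, a retinoic acid receptor, from 0.507 ± 0.0887 to 13.4 ± 3.09 CPM. The transcription factor gene Bcl11a had a log2 fold change of 4.71, the dystrophin gene Dmd 4.44 and the LIM-domain gene Fhl1 4.41. Gpr35, the connexin gene Gjb5 and Ass1, which encodes argininosuccinate synthase, reached 4.29, 4.26 and 4.06. Bcl11a and Dmd moved to 5.54 and 5.14 without wild-type library 2, and Kctd12 to 4.27 without labelled library 1. All 20 of these genes kept their calls without each library in turn.

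**Figure D3:**
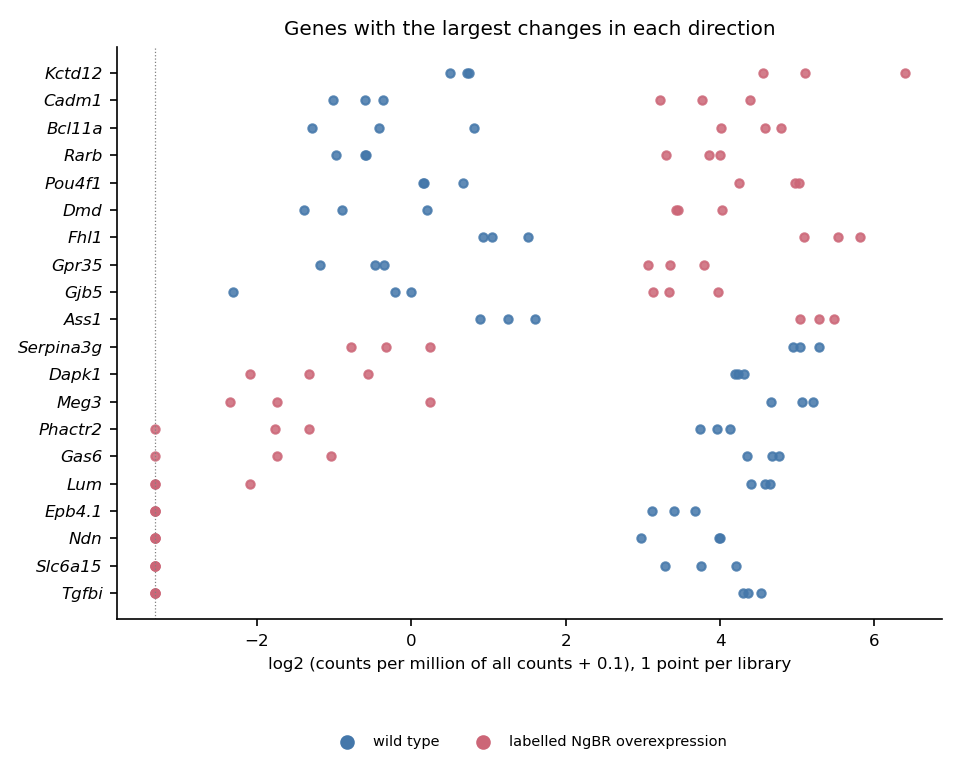
The 10 called genes with the largest increase and the 10 with the largest decrease, as log2 of CPM over all counts plus 0.1, 1 point per library. Only genes with a mean of at least 5 CPM, separate ranges of the groups and a symbol that is not one of a predicted gene were ranked. The dotted line marks 0 counts, where all 3 libraries labelled NgBR overexpression lie for Tgfbi, Slc6a15, Ndn and Epb4.1.

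Gene lists were compared next, and 16 of 33 were called by camera with its preset correlation, 11 higher and 5 lower in the libraries labelled NgBR overexpression. With an estimated correlation 0 lists were called, 2 at an unadjusted p under 0.05, and fry called 2, the Hox and the bone and cartilage genes (adjusted p = 0.0247 each). Another split of the 6 libraries into 3 and 3 also gave 16 lists with the preset correlation. Without labelled library 1, camera called 10 lists.

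Hypoxia target genes and Hox genes had the largest median increases among the tested lists. All 18 tested hypoxia targets had positive fold changes, with a median log2 fold change of 1.23, and 6 rose over all genes tested, 12 adjusted over the list alone (camera adjusted p = 2.44e-12, adjusted p = 0.354 with an estimated correlation). Egln1, an oxygen-sensing prolyl hydroxylase, rose from 76.5 ± 15.5 to 308 ± 105 CPM (log2 fold change 2.01, SE 0.31, edgeR adjusted p = 0.0076). Mxi1, a MYC antagonist, rose with a log2 fold change of 1.56 (SE 0.26, edgeR adjusted p = 0.0108). Ndrg1 and Bnip3, a mitophagy receptor, had log2 fold changes of 2.0 and 1.87. The list means lay 0.57, 1.61 and 1.43 above the wild-type mean in labelled libraries 1 to 3. Of the 6 hypoxia targets called, 2 kept their calls without each library in turn. Ndrg1 was not called without wild-type libraries 1 or 3 or labelled libraries 1, 2 or 3 (edgeR adjusted p = 0.0886, 0.0703, 0.0505, 0.078 and 0.0772). Bnip3 was not called without wild-type libraries 1, 2 or 3 or labelled libraries 2 or 3 (edgeR adjusted p = 0.0885, 0.0926, 0.0671, 0.0525 and 0.0757).

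Of 21 tested glycolysis genes, 1 rose over all genes and 4 adjusted over the list alone, with a median log2 fold change of 0.60 (camera adjusted p = 9.31e-06, adjusted p = 0.392 with an estimated correlation). Hk1, a hexokinase, rose from 159 ± 23.4 to 473 ± 147 CPM (log2 fold change 1.57, SE 0.29, edgeR adjusted p = 0.0184). Its call was lost without wild-type libraries 1, 2 or 3 or labelled library 1 (edgeR adjusted p = 0.0631, 0.0658, 0.0766 and 0.0793). Pkm and Gapdh had log2 fold changes of 0.39 and 0.58 and were not called. None of 33 oxidative phosphorylation genes was called (median log2 fold change -0.08, camera adjusted p = 0.364). The 11 mitochondrially encoded genes were all negative with 0 called, a median of -0.87 (camera adjusted p = 0.000192, adjusted p = 0.523 with an estimated correlation), but the list means of the groups overlapped, at 0.41, -0.57 and 0.16 in wild-type libraries 1 to 3 and -0.63, -1.82 and -0.46 in labelled libraries 1 to 3.

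Of 26 tested Hox genes, which specify position along the body axis, 11 rose over all genes and 16 adjusted over the list alone, with a median log2 fold change of 1.61 (camera adjusted p = 2.44e-12, adjusted p = 0.354 with an estimated correlation). Hoxc10 rose from 0.713 ± 0.169 to 10.6 ± 5.36 CPM (log2 fold change 3.87, SE 0.48, edgeR adjusted p = 0.00293) and Hoxb5 from 0.379 ± 0.0393 to 4.39 ± 1.33 CPM. Hoxa13 reached 3.74 ± 3.07 CPM from 0.0421 ± 0.0221 CPM, and its log2 fold change of 6.31 was 5.44 without labelled library 2. Hoxa13 and Hoxd11 were below the filter, and so not tested, with all libraries thinned to the shallowest depth. The same held with the minimum of 1 CPM in 3 libraries. Of the 11, 6 kept their calls without each library in turn. Hoxd11 had a log2 fold change of 3.86 and was not called without labelled libraries 1 or 2 (edgeR adjusted p = 0.0793 and 0.0536), nor was Hoxc9 without labelled libraries 1 or 3 (0.0892 and 0.0674). Hoxc4 was not called without wild-type libraries 2 or 3 or labelled libraries 1 or 3 (0.0535, 0.0561, 0.0831 and 0.0656). Hoxb4 was not called without wild-type libraries 2 or 3 or labelled libraries 1 to 3 (0.0518, 0.0877, 0.125, 0.0717 and 0.0792), nor Hoxb8 without wild-type libraries 1 to 3 or labelled libraries 1 or 3 (0.12, 0.0603, 0.0925, 0.126 and 0.0818). Antisense transcripts lie in these clusters, and with the strand setting unknown their reads cannot be told apart from those of the Hox genes.

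Of 6 tested bone and cartilage genes, Bmp4, a morphogen of the TGF-beta family, rose from 0.218 ± 0.0667 to 2.76 ± 1.17 CPM, and 1 gene passed adjusted over the list alone (camera adjusted p = 0.0154, adjusted p = 0.354 with an estimated correlation). Sox9 and Matn2 had log2 fold changes of 0.51 and 0.20 and were not called. Of 6 tested neural markers, 1 rose over all genes and 3 adjusted over the list alone (camera adjusted p = 0.000802, adjusted p = 0.354 with an estimated correlation). That gene, Syt1, named after its values were seen, had 2 counts over the wild-type libraries and 17 over the others, and was below the filter whichever library was left out. Map2 had a log2 fold change of 1.58 (edgeR adjusted p = 0.0562). The neural list lost its call without labelled libraries 1, 2 or 3 (camera adjusted p = 0.746, 0.13 and 0.299). Lists of epithelial, endothelial, leukocyte and skeletal muscle markers had 2, 3, 3 and 3 tested members, too few for camera, with 0 called over all genes. Adjusted over the list alone, 2 of the skeletal muscle markers rose, Tnnt2 and Des with log2 fold changes of 2.72 and 1.37, and 0 markers passed in the other 3 lists.

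Matrix genes were tested as a collagen list, called higher, and a non-collagen list, called lower. Of 29 tested members of the collagen list, 4 rose and 1 fell, and 8 passed adjusted over the list alone (camera adjusted p = 0.00252, adjusted p = 0.523 with an estimated correlation). The genes that rose encode enzymes that modify collagen. Plod2, a lysyl hydroxylase, rose from 32.3 ± 5.11 to 151 ± 51.2 CPM (log2 fold change 2.22, SE 0.30, edgeR adjusted p = 0.00388). P4ha2, a prolyl hydroxylase, rose with a log2 fold change of 1.44, Loxl3, a lysyl oxidase, with 1.13, and Plod1, named after its values were seen, with 1.12. Col5a3 fell from 11.1 ± 4.85 to 2.43 ± 1.15 CPM. P4ha2 lost its call without wild-type libraries 1, 2 or 3 (edgeR adjusted p = 0.0683, 0.0506 and 0.0541), and Col5a3 without wild-type library 2 or labelled libraries 1, 2 or 3 (0.0832, 0.0892, 0.0867 and 0.0952). Loxl3 and Plod1 lost theirs without each of the 6 libraries, wild-type libraries 1 to 3 (0.111, 0.085 and 0.112 for Loxl3, 0.118, 0.0666 and 0.11 for Plod1) and labelled libraries 1 to 3 (0.178, 0.091 and 0.0592 for Loxl3, 0.0548, 0.0545 and 0.0683 for Plod1). The list itself was not called without labelled library 2 (camera adjusted p = 0.137).

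Of 29 tested genes of the non-collagen matrix, 3 fell over all genes and 6 passed adjusted over the list alone, 5 lower and 1 higher (camera adjusted p = 0.0105, adjusted p = 0.524 with an estimated correlation). Besides Lum, Nid2, a basement membrane protein, fell from 33.3 ± 4.32 to 5.92 ± 0.965 CPM (log2 fold change -2.49, SE 0.25, edgeR adjusted p = 0.000899), and Fbln1 fell from 4.17 ± 0.858 to 0.285 ± 0.287 CPM. The log2 fold change of Fbln1, -3.83, was -3.21 without labelled library 2 and -5.07 without labelled library 3. Fbln1 was not called without labelled library 1 (edgeR adjusted p = 0.0892), nor was the list without labelled libraries 1 or 3 (camera adjusted p = 0.155 and 0.191) or without a filter on low counts (0.0582).

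Of 22 tested cytokine, chemokine and NF-kB target genes, 2 fell, both also adjusted over the list alone, and 18 were negative (camera adjusted p = 0.000463, adjusted p = 0.523 with an estimated correlation). Saa3, an acute-phase protein, fell from 273 ± 53.5 to 20.5 ± 12.6 CPM (log2 fold change -3.72, SE 0.51, edgeR adjusted p = 0.0044) and Cxcl12, a chemokine, from 141 ± 7.13 to 20.2 ± 4.83 CPM (log2 fold change -2.80, SE 0.25, edgeR adjusted p = 0.000635). Interferon response genes had 0 of 23 called, with 22 negative (camera adjusted p = 0.0067, adjusted p = 0.354 with an estimated correlation), and lost the list call without labelled library 1 (0.0631) or without a filter on low counts (0.179). Lysosome genes had 0 of 23 called, with 20 negative (camera adjusted p = 0.0081, adjusted p = 0.523 with an estimated correlation), and lost it without labelled libraries 1 or 2 (0.0659 and 0.0898).

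Angiogenic growth factors and receptors went both ways. Of 26 tested, 4 rose and 3 fell, 8 adjusted over the list alone, and the list was not called (camera adjusted p = 0.697). Pgf, placental growth factor, rose from 0.222 ± 0.0811 to 4.64 ± 1.22 CPM, and Igf1 had a log2 fold change of 1.81. Ptn, pleiotrophin, fell from 204 ± 97.1 to 26.5 ± 12.3 CPM and Flt1, a VEGF receptor, from 15.2 ± 1.39 to 3.08 ± 1.34 CPM. Of the 7 called, 1 kept its call without each library in turn. Igf1 was not called without wild-type library 3 or labelled libraries 1, 2 or 3 (edgeR adjusted p = 0.0553, 0.123, 0.0958 and 0.0682). Ptn and Flt1 were not called without labelled library 1 (edgeR adjusted p = 0.0865 and 0.051).

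**Figure D4:**
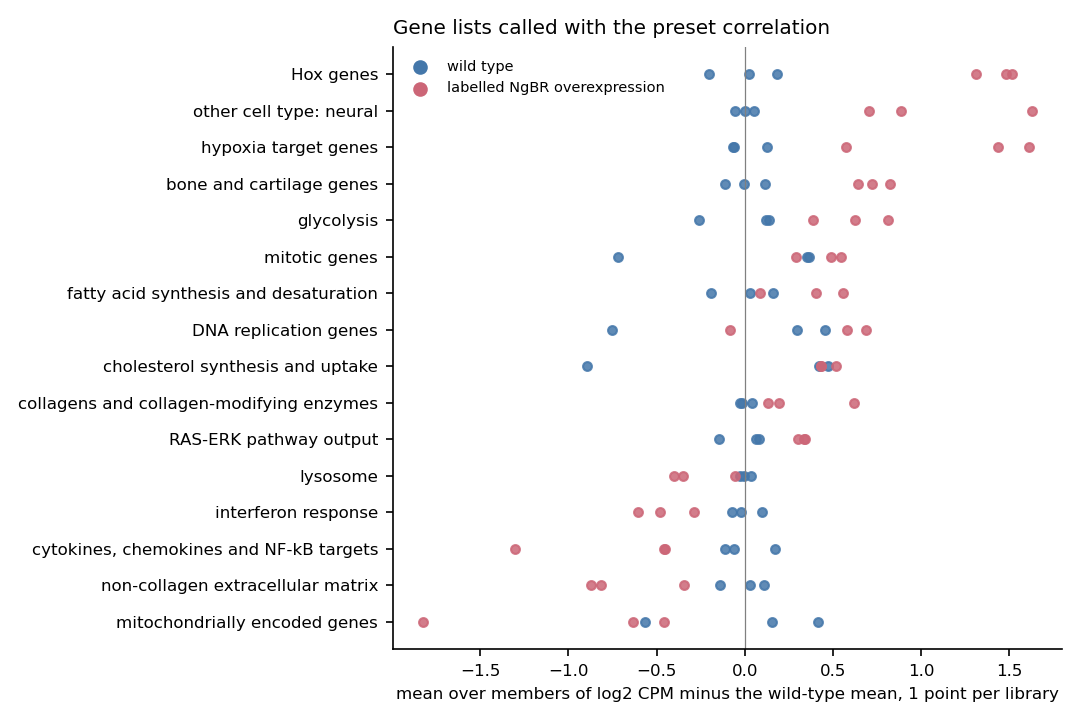
The 16 gene lists called by camera with the preset correlation, each as the mean over its members of log2 CPM minus the wild-type mean, 1 point per library. Hox genes lie at 1.31 to 1.51 in the libraries labelled NgBR overexpression, and mitotic, DNA replication and cholesterol genes are lowest in wild-type library 2.

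The dolichol, cholesterol and fatty acid lists held few called genes. None of 33 genes of dolichol synthesis and N-glycosylation was called by edgeR, over all genes or adjusted over the list alone (median log2 fold change -0.12, camera adjusted p = 0.597). Rpn1 and Stt3b, subunits of the oligosaccharyltransferase, had log2 fold changes of -0.29 and 0.19. Cholesterol synthesis and uptake had 0 of 23 called and 21 positive (camera adjusted p = 0.00373, adjusted p = 0.821 with an estimated correlation). Wild-type library 2 lay at -0.89 for this list and the other libraries at 0.42 to 0.52, and the list call was lost without it (camera adjusted p = 0.693). Of 13 cholesterol trafficking and efflux genes 1 rose, also adjusted over the list alone, Abcg1, a sterol exporter, from 0.158 ± 0.137 to 2.67 ± 0.246 CPM (log2 fold change 4.0, SE 0.58, edgeR adjusted p = 0.00534, and 4.96 without wild-type library 1). That list was not called (camera adjusted p = 0.651). Fatty acid synthesis had 0 of 14 called, 1 adjusted over the list alone (camera adjusted p = 0.0255, adjusted p = 0.524 with an estimated correlation), and lost its call without wild-type library 2 or labelled libraries 1 or 2 (0.12, 0.155 and 0.13).

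Cell cycle lists held 0 called genes by edgeR. All 26 mitotic genes (median log2 fold change 0.36) and 29 of 31 DNA replication genes (0.35) were positive, with camera adjusted p = 0.000976 and 0.00331, and adjusted p = 0.677 and 0.833 with an estimated correlation. Their list means were -0.72 and -0.75 in wild-type library 2, without which neither was called (camera adjusted p = 0.378 and 0.641), and DNA replication was not called without labelled library 1 (0.174). Without both libraries numbered 2, DNA replication kept its call and the mitotic list lost it (0.0762). The DNA replication mean was -0.08 in labelled library 2. It was 0.69 and 0.58 in labelled libraries 1 and 3, against 0.30 and 0.46 in wild-type libraries 1 and 3. Mki67, a proliferation marker, had a log2 fold change of 1.12 (edgeR adjusted p = 0.386).

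Signalling targets gave single genes. Of 23 genes of RAS-ERK output 1 rose, also adjusted over the list alone, the ERK phosphatase gene Dusp5, from 22.9 ± 2.15 to 46.8 ± 7.19 CPM (edgeR adjusted p = 0.0333, list by camera 0.00624, adjusted p = 0.354 with an estimated correlation). Dusp5 lost its call without wild-type libraries 1, 2 or 3 or labelled libraries 1 or 3 (0.186, 0.0783, 0.11, 0.148 and 0.0828), and the list lost its own without wild-type library 1 (0.0547). Of 22 immediate early genes 2 rose and 5 passed adjusted over the list alone, 3 higher and 2 lower. Ier3 and Dusp1 had log2 fold changes of 1.58 and 1.35, and the list was not called (camera adjusted p = 0.898). Ier3 was not called without wild-type libraries 1 or 2 or labelled libraries 2 or 3 (0.0686, 0.06, 0.052 and 0.065), nor Dusp1 without wild-type libraries 1, 2 or 3 or labelled library 3 (0.0972, 0.0601, 0.0565 and 0.061). Of 17 FOXO targets Ccng2 rose and Sod2, mitochondrial superoxide dismutase, fell, both also adjusted over the list alone, with log2 fold changes of 1.83 and -1.50 (camera adjusted p = 0.521). Ccng2 was not called without wild-type libraries 1 or 2 or labelled library 3 (0.0501, 0.0662 and 0.058), nor Sod2 without labelled library 1 (0.0532).

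Of 18 TGF-beta targets 4 rose and 1, Tgfbi, fell, and 7 passed adjusted over the list alone, 4 higher and 3 lower (camera adjusted p = 0.288). Bhlhe40, a circadian repressor, rose from 18.5 ± 3.96 to 89.2 ± 30.7 CPM (log2 fold change 2.27, SE 0.31, edgeR adjusted p = 0.00402). Smad7, an inhibitory SMAD, had a log2 fold change of 1.29. The median of the list was 0.23, with Tgfbi at its bound too, but the mean was -0.33, or -0.10 with Tgfbi at its bound, and fry pointed down. Of the 5 TGF-beta targets called, 2 kept their calls without each library in turn. Smad7 was not called without wild-type libraries 1 or 3 (0.131 and 0.0679) or labelled libraries 1 to 3 (0.0926, 0.0784 and 0.0674).

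Of 21 matrix proteases and inhibitors 2 rose, among them Ctsk, cathepsin K, and 4 passed adjusted over the list alone, 2 higher and 2 lower (camera adjusted p = 0.785). Ctsk had a log2 fold change of 2.40 and was not called without wild-type library 1 or labelled libraries 1 or 3 (0.0539, 0.0712 and 0.0568). Of 19 contractile genes Tagln, a smooth muscle protein, fell from 21.6 ± 1.44 to 8.41 ± 2.06 CPM, and 4 passed adjusted over the list alone, 3 lower and 1 higher (camera adjusted p = 0.785). Tagln was not called without wild-type libraries 1 or 3 or labelled library 1 (0.106, 0.0671 and 0.0917). Of 8 adipocyte genes Lpl, lipoprotein lipase, fell, also adjusted over the list alone, from 222 ± 89.1 to 63.0 ± 32.3 CPM (camera adjusted p = 0.898), and was not called without wild-type libraries 1 or 2 or labelled libraries 1 or 3 (0.0668, 0.138, 0.235 and 0.152). In the contractile and adipocyte lists the medians were 0.01 and 0.05 where mean and test were negative, and in the immediate early list the median was -0.15 where the test was positive.

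The other lists had 0 called genes by edgeR, over all genes or adjusted over the list alone, and were not called by camera. They were epithelial-mesenchymal transition genes (15 tested, camera adjusted p = 0.132), YAP-TEAD targets (15, 0.697), p53 targets (19, 0.904), the unfolded protein response (26, 0.232), NRF2 targets (23, 0.822), histones (16, 0.354) and cytosolic ribosomal proteins (37, 0.288). Fn1, Vim, Hspa5 and Rplp0 from these lists had log2 fold changes of -0.04, 0.37, -0.78 and -0.11.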

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

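Thinning to the shallowest library, length and GC offsets, leaving out both libraries numbered 2 and protein-coding genes only were added after seeing the data. The cause of each shift was not tested, unless the alternative itself means fewer libraries. Nus1 was not called and stayed negative under the alternatives run for it, which leave out the test against a 1.5-fold change, at -0.32 to -0.17 with each library left out. The number of called genes was 726 with DESeq2 (456 higher, 270 lower, 671 changed 2-fold) and 688 without a filter (302 lower, 682 changed 2-fold). It was 225 to 374 with each library left out, for all calls and for those changed 2-fold, with 141 to 209 higher and 84 to 165 lower. Calls lower numbered 113 against a 1.5-fold change and 263 without both libraries numbered 2, where 361 of 581 calls were shared with the 429. At equal depth 325 genes were called, 318 of them shared. Without a filter the median log2 fold change of all genes was -0.11.

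With the replicate number as a block, 719 genes were called (418 higher, 301 lower, 643 changed 2-fold). Deviations from the group means correlated across genes at 0.0147, 0.341 and 0.434 for libraries numbered 1, 2 and 3. Pairs of unlike number across the groups gave -0.399 to 0.189, the highest for wild-type library 1 with labelled library 3. Whether libraries of the same number share more than the number is not settled by these values.

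Lists called numbered 10 to 17 with each library left out, 0 with an estimated correlation and 2 with fry. At equal depth 14 lists were called. The bone and cartilage list and the neural list had fewer than 5 tested members at that depth and were not tested. Bmp4, Hoxa13 and Hoxd11 were also below the filter at equal depth. Cholesterol synthesis turned its direction without both libraries numbered 2 (camera adjusted p = 0.926, against 2.09e-05 to 0.693 with each library left out). The fold change of Dhdds, not called, turned negative without a filter (-0.00549), at equal depth (-0.0269), without both libraries numbered 2 (-0.0825), and was -0.182 to 0.226 with each library left out. Of 54 called named genes besides Nus1 and Dhdds, 33 kept their calls without each of the 6 libraries, as did 6 of 16 lists. Without both libraries numbered 2, calls were lost by the lists of collagens (camera adjusted p = 0.161), fatty acid synthesis (0.28), mitotic genes (0.0762) and neural markers (0.184), and by Bnip3, Col5a3, Hoxd11, Ier3 and Loxl3 (edgeR adjusted p = 0.0592, 0.053, 0.0601, 0.059 and 0.0514). Col5a3 was not called by limma-voom (0.0555), Dusp5 not at equal depth (0.062), and Lpl neither with RLE factors (0.0515) nor with the 1 CPM minimum (0.0557). Depth limits the lowest levels: 3 counts over the libraries labelled NgBR overexpression are 0.108 CPM.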

Other observations

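The tests of depth, exchanged libraries, transgene reads, sublines and the Y chromosome, and those on developmental genes, imprinted genes and processed pseudogenes, were chosen after the results they concern had been seen.

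Outside the Hox clusters, some transcription factor genes of development were called. Of 73 tested, 12 rose, 1, Gata6, fell and the rest were not called, with a median log2 fold change of 0.20, against 1.96% of the other genes called higher (Fisher's exact test, 2-sided, p = 2.445e-08). The families were picked with the calls in view, so that this p is no independent evidence. Pou3f2 rose from 0.198 ± 0.0655 to 9.05 ± 4.61 CPM, Foxp2 from 0.895 ± 0.636 to 12 ± 3.05 CPM and Pax6 from 0.306 ± 0.174 to 5.12 ± 2.53 CPM (SD, n = 3), and all 3 kept their calls without each library in turn. Without wild-type library 2 the log2 fold change of Foxp2 was 4.48, against 3.75 with all libraries. Of the 12 that rose, 9 kept their calls without each library. Prox1 lost its own without wild-type libraries 1 or 2 or labelled libraries 1 or 2 (edgeR adjusted p = 0.0628, 0.0658, 0.0892 and 0.0917), Sall1 without labelled libraries 1 or 2 (0.0849 and 0.0576), and Satb1 without wild-type libraries 1 or 3 or labelled libraries 1 or 3 (0.0856, 0.0686, 0.101 and 0.0786). Gata6 had a log2 fold change of -1.38 and lost its call without wild-type libraries 1, 2 or 3 (edgeR adjusted p = 0.147, 0.0613 and 0.154) or labelled libraries 1, 2 or 3 (0.0693, 0.0682 and 0.104).

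Of 26 imprinted genes, 5 were called, and all of these fell, against 3.36% of other genes called (Fisher's exact test, 2-sided, p = 0.001598). They were Ndn, H19, Meg3, Rian and Mirg. The last 3 lie side by side on chromosome 12, between 109541001 and 109749460, and were not independent of each other. The test counts them as separate genes and was chosen with the calls in view, so that its p is no independent evidence. H19 fell from 17.8 ± 4.79 to 2.10 ± 0.927 CPM and Rian from 25.2 ± 10.3 to 0.562 ± 0.459 CPM (log2 fold change -5.38, or -6.18 without labelled library 3). Mirg was not called without wild-type libraries 1 or 3 (edgeR adjusted p = 0.0683 and 0.0562) or labelled libraries 1 or 2 (0.0831 and 0.0643).

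Nus1 was not higher in the libraries labelled NgBR overexpression. Too few counts would leave room for a doubling, but the upper 95% bound of its log2 fold change was 0.2356. An exchange of 1 or 2 libraries between the groups would break up genes absent from 3 libraries, but of the genes with 0 counts in 3 libraries and at least 20 in each of the others, 16 had these in the libraries labelled NgBR overexpression and 0 in a set of 3 that mixed the groups. An exchange of the whole groups stays open, because the highest Nus1 CPM, 1.408 times the lowest, speaks to it only if reads of the transgene were counted at mouse Nus1. A transgene whose reads were not counted at mouse Nus1 stays open as a candidate explanation, because the table held 0 rows for anything but mouse Ensembl genes.

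Processed pseudogenes called by edgeR were all higher in the libraries labelled NgBR overexpression, 29 higher and 0 lower of 331 tested, against 219 and 167 of the protein-coding genes (Fisher's exact test, 2-sided, p = 3.36e-07). This p is of the pattern that prompted the test and is no independent evidence. Reads shared with parent genes that rose are argued against as the whole cause, since the median log2 fold change of 27 distinct parents was 0.1687 (95% interval -0.0127 to 0.288) and 0 were called. A general move of reads to near-identical copies would raise all of these, but 255 pseudogenes at least 98% identical to a coding transcript had a median of 0.0331 (-0.0297 to 0.108). Genomic DNA would raise silent genes, but pooled CPM over 1578 olfactory and vomeronasal receptor genes differed by a ratio of 1.096 (0.943 to 1.27). A difference in these loci between the cell lines was not tested.

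In the libraries labelled NgBR overexpression, 34 genes called lower had 3 counts or fewer in all, 18 of them 0. Lower depth alone would leave as many genes near 0 in thinned wild-type libraries. Of 13002 genes with at least 10 counts expected, 125 had 3 or fewer in the libraries labelled NgBR overexpression, against at most 3 in 20 thinnings of the wild-type libraries to the same depths, where 0 of the 34 were that low. Loss of contiguous chromosome segments would place them side by side, but 0% of the 33 genes off the Y chromosome had an adjacent tested gene in the set. With neighbours below the filter, at 5 expected counts or more, 2 of the 33 had one at 3 counts or fewer. For Ddx3y a loss of the Y chromosome stays open, since Kdm5d, Eif2s3y and Uty also had 0 counts, which does not tell loss from silencing. A difference between sublines or clones that has nothing to do with NgBR could account for them and stays open, because 0 libraries of a vector-only line were there to compare. An effect of NgBR stays open as well and was not tested.

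The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 241 counts over the wild-type libraries and 0 over the libraries labelled NgBR overexpression, where 68.3 were expected. Erdr1, annotated on Y but pseudoautosomal, was left out of this sum and had 128, 43 and 368 counts in labelled libraries 1 to 3. Among genes that were not called, the log2 fold changes of adjacent genes correlated at 0.114 across genes, above 0.0302, the highest of permuted orders, and copy-number differences between the lines could not be settled from this value.

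Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 429 genes and the highest other split 0, so that 1 of the 10 gave as many genes. At an unadjusted p under 0.05 by edgeR, the real split gave 1444 genes. The split of wild-type libraries 1 and 3 with labelled library 3 against the rest gave 1988, and the other splits 74 to 808. For lists, the real split gave 16 and the highest other 16, so that 2 of the 10 gave as many. The labels give no batch or date, and a difference in preparation or sequencing that runs with the groups, as the 3.50-fold difference in mean depth does, cannot be told apart from the cell lines in these calls.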
